A study of Homo sapiens with 7 samples.

How the data were processed

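CyT49 human embryonic stem cells were differentiated toward pancreas, and chromatin was immunoprecipitated for HNF6 on day 5 and day 10, for GATA6 on day 10 and for NKX6.1 on day 13, per the labels. Of the 7 samples, 4 had a peak list and 3 were inputs of days 5, 10 and 13, which the labels describe as controls and which were not analysed here. Groups were taken from the sample titles. The antibody given as a sample characteristic matched the title of each peak list, whereas the extraction protocol of every sample names an antibody against NKX6.1 and mentions days 5 and 10 only, per the labels' protocols. The input of day 13 carries NKX6.1 as its antibody characteristic and was grouped as an input by its title. The day 5 title gives the factor as HNF, and its antibody characteristic as HNF6.

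Bowtie2 2.3.4.1, MACS2 2.1.1.20160309 and the genome build hg19 are named, with neither roles nor settings, per the submitters' processing notes. The authors deposited 1 list per library, with no header, that gives position, peak name and a score per peak. The unit of the deposited score is not given in the sources used here. Scores are whole numbers of at least 13 (22 in the day 5 list). They were used only to rank or filter regions within a list, and scores of different lists were not compared. A filter at this lower end and the authors' use of the inputs would set which weak regions appear in a list. A list from a deeper library holds more regions, and read depth, fragments per region and the false discovery rate are unknown from the lists.

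The lists held 255 (HNF6 day 5), 66373 (HNF6 day 10), 6556 (GATA6) and 14793 (NKX6.1) rows. Rows with the same start and end, which carry the same peak number with a letter, were merged to 1 region with the highest score, which left 250, 64919, 6285 and 14627 regions. Summit positions were not used here, and midpoints stood in for them. Peak numbers were complete in the other lists, but the GATA6 list gave 6285 of 19404 numbers, and each listed region overlapped an HNF6 region of day 10. Regions on unplaced contigs (25 for HNF6 day 10, 1 for GATA6 and 15 for NKX6.1) were kept in counts of overlap and left out of shifts, distances and windows.

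Overlap was counted from 1 bp with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and the counts equalled those of bedtools 2.31.1 for all pairs of lists reported. Shares are given with Wilson 95% intervals (statsmodels 0.14.6), which cover counting error only. Chance was the mean over 1000 circular shifts of the first list within each chromosome, whose length was taken as the farthest position in any list. Such shifts also place regions in closed chromatin, so the ratio to chance holds whatever is common to accessible sites. For regions with all 3 factors the NKX6.1 list was shifted, in place of the first list named in the plan, since each listed GATA6 region overlaps HNF6. Spearman's rho (scipy 1.17.1) is across regions or windows, which are not independent replicates. Odds ratios are Mantel-Haenszel ratios over HNF6 score or width deciles, or over 89 strata of both with at least 20 regions.

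The code was tested on simulated data. With 0, 10 and 40% of 5000 regions planted on HNF6 day 10 regions, 39, 537 and 2020 overlaps were found where 42.5, 539 and 2026 were wanted. For the comparison of NKX6.1 by GATA6 at HNF6 regions, the stratified odds ratio was 1.02 for a true ratio of 1 and 2.97 for a true ratio of 3. Both simulated partners depended on the decile alone. The simulation thus tested the code, and not whether deciles remove all effect of score in the data.

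Tests, groups, alternatives and the rule for named regions were fixed before the data were examined. The rule takes the 10 strongest regions of each list, the 10 strongest day 5 regions with and without a day 10 region, and the 10 regions of all 3 factors with the best mean rank. The alternatives fixed in this way were overlap of 50% of the shorter region, midpoints within 200 bp, the regions above the median score of each list, equal numbers of strongest regions, and shifts of 20 to 200 kb. Chosen after seeing the data were scores of at least 50, the odds ratios, the 1000 draws matched on score percentile (200 bins) with all their measures, chromosome shares, score quartiles and deciles, midpoint distances (NKX6.1 regions without overlap were set beside shifted regions without overlap), all alternatives for day 5 HNF6 at GATA6 and at NKX6.1, neighbours within 12.5 kb (100 random placements), and windows of 1 Mb. Position relative to genes, genes near regions and motifs were planned and not run, because neither an hg19 gene annotation nor an hg19 sequence was used here. Regions are therefore named by position alone, 1-based on hg19. With 1 library per group no test across replicates applied, and no p-value was computed.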

Results

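Chromatin occupancy of 3 transcription factors was profiled by chromatin immunoprecipitation and sequencing while CyT49 cells, an established human embryonic stem cell line, were differentiated in vitro toward pancreas. HNF6, also named ONECUT1, is a homeodomain factor of liver and pancreas development. GATA6 is a zinc finger factor needed for formation of the human pancreas. NKX6.1 is a homeodomain factor of pancreatic progenitors and later of beta cells. HNF6 was profiled on day 5, at the gut tube endoderm stage, and on day 10, in pancreatic progenitors. GATA6 was profiled on day 10 and NKX6.1 on day 13. Each combination of factor and day had 1 library, so no difference below has a replicate check and no p-value is given. The 3 input libraries were not analysed here.

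The number of occupied regions differed widely between the lists. The HNF6 list of day 5 held 250 distinct regions with a median width of 221 bp, which covered 0.0607 Mb. On day 10 the HNF6 list held 64919 regions with a median width of 261 bp, which covered 18.8 Mb, and was 260 times as long as that of day 5. The GATA6 list held 6285 regions (median width 285 bp, 2.0 Mb in all). The NKX6.1 list held 14627 regions, which were the narrowest, with a median width of 99 bp and 1.60 Mb in all. Its smallest region was 76 bp wide, against 175 to 179 bp in the other lists. Whether its peaks were called with other settings is not given in the sources used here. The authors' peak score had a median of 122 in the day 5 HNF6 list, 79 in the day 10 HNF6 list, 102 in the GATA6 list and 55 in the NKX6.1 list. The scores were used only to rank regions within their own list. Read depth is unknown from the lists, so the number of regions per library cannot be set against it. The GATA6 list was partial: its peak numbers ran to 19404, of which 32.4% were listed, and 13119 numbered peaks were not analysed here.

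The comparison of HNF6 on day 5 and day 10 asked where the same factor was found at both stages. Nearly all regions of day 5 were also regions of day 10: 226 of 250, or 90.4% (Wilson 95% interval 86.1 to 93.5), overlapped by at least 1 bp. When the day 5 regions were shifted around their chromosomes 1000 times, a mean of 2.75 overlapped (range 0 to 10), so the observed number was 82.2 times that of random placement (84.1 to 1667 times under the alternatives, highest with equal numbers of strongest regions). The highest ratio rests on a mean of only 0.021 regions by chance. In the opposite direction, 225 of the 64919 regions of day 10, or 0.347% (0.304 to 0.395), overlapped a region of day 5. In the overlapping pairs the midpoints lay a median of 30 bp apart, and 64.2% of pairs lay within 50 bp. The intervals cover counting error only, because regions are not independent samples. With equal numbers of strongest regions, the day 5 list stayed whole and the day 10 list was cut to its 250 strongest. Then 35 (14.0%) were shared, so 215 of the 250 strongest day 10 regions overlapped no region of the day 5 list.

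The strongest HNF6 regions of day 5 were all found again on day 10. The strongest lay on chromosome 20 at 32319809 to 32320220 (hg19, score 991), followed by chromosome 8 at 41909404 to 41909794 (score 929) and chromosome 11 at 65686623 to 65687057 (score 893). The next were on chromosome 8 at 144679587 to 144679924 (score 665) and on chromosome 19 at 461854 to 462230 (score 632). All 10 of the strongest regions of day 5 overlapped an HNF6 region of day 10, 8 overlapped a listed GATA6 region and 0 overlapped an NKX6.1 region. The share that overlapped day 10 was 82.5% (71.4 to 89.96) in the lowest score quartile of day 5 and 100% (94.3 to 100) in the highest. The 24 regions of day 5 without a region of day 10 had a median score of 84.5, against 127 for the 226 with one. The strongest of the 24 lay on chromosome 19 at 17186263 to 17186489 (score 203), chromosome 19 at 48281734 to 48281935 (score 140) and chromosome 17 at 34136118 to 34136427 (score 134).

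Among the day 10 regions, those already present on day 5 were spread over the upper part of the score range. Their median lay at the score percentile 84.7 of all HNF6 regions of day 10 (quartiles 63.8 and 99.2), and 97 of the 225 (43.1%) were in the highest score decile. In 33 of the 226 pairs (14.6%) the day 10 region lay below the median score of its list. The ranks of the paired regions by score on day 5 and day 10 had a Spearman's rho of 0.01 across the 226 pairs, which are not independent replicates. The strongest HNF6 region of day 10, on chromosome 19 at 1725173 to 1726300 (score 4510), was in place on day 5 and overlapped a listed GATA6 region. The next were on chromosome 9 at 110309093 to 110309737 (score 4237) and on chromosome 15 at 71698502 to 71699087 (score 4164), neither of which was in the day 5 list. The region on chromosome 7 at 83807179 to 83807759 (score 3818) overlapped regions of all other lists. Of the 10 strongest HNF6 regions of day 10, 3 overlapped a day 5 region, 9 a listed GATA6 region and 5 an NKX6.1 region.

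HNF6 regions were distributed differently over the chromosomes on the 2 days. Chromosome 19 held 7.6% (4.92 to 11.6) of the day 5 regions and 1.09% (1.02 to 1.18) of the day 10 regions. Chromosome 17 held 6.4% (3.98 to 10.1) against 2.24% (2.12 to 2.35), and chromosome 22 held 3.6% (1.91 to 6.70) against 0.738% (0.675 to 0.807). Chromosome 2 held less on day 5, with 4.0% (2.19 to 7.21) against 9.05% (8.83 to 9.28). At equal list length, with the 250 strongest day 10 regions, only chromosome 2 of these 4 kept intervals apart from day 5, at 12.0% (8.54 to 16.6). Chromosome 17 then held 5.6% (3.36 to 9.18), close to day 5, and the intervals of chromosome 19 (2.8%, 1.36 to 5.67) and chromosome 22 (1.2%, 0.409 to 3.47) overlapped those of day 5.

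**Figure D1:**
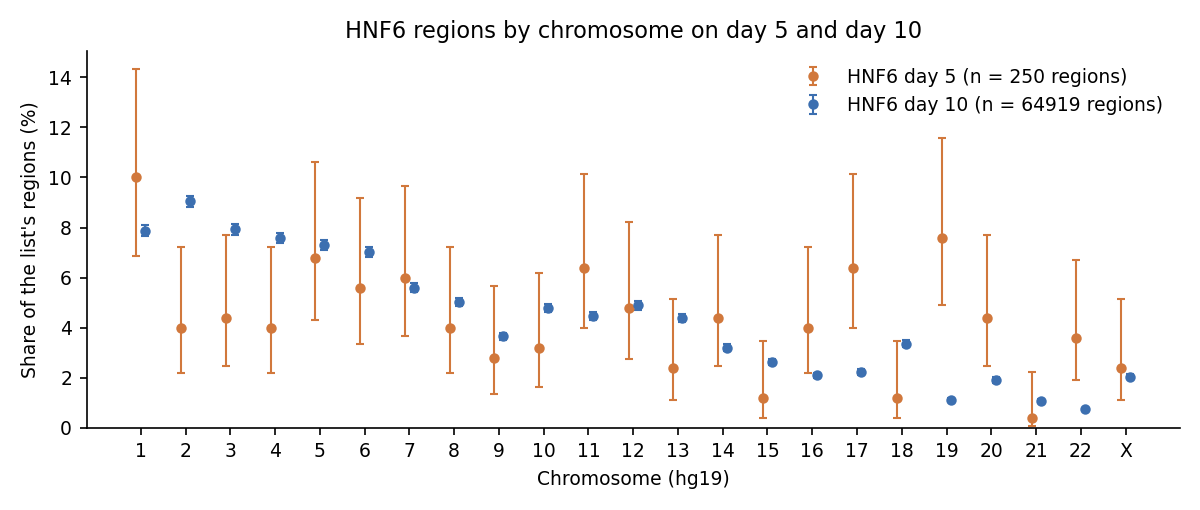
Share of HNF6 regions on each chromosome (hg19, in percent of the list) on day 5 (orange, 250 regions) and day 10 (blue, 64919 regions), with Wilson 95% intervals as bars. Chromosome 19 held 7.6% of the day 5 regions and 1.09% of the day 10 regions, and chromosome 2 held 4.0% and 9.05%.

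The 225 day 10 regions present on day 5 were set beside 1000 draws of other HNF6 regions of day 10 matched on score percentile, a comparison added after the data had been examined. Chromosome 19 held 7.56% of the 225 regions and a mean of 1.40% of the draws (highest 4.89%). NKX6.1 was found at 3.11% of the 225 regions, or 7 regions, and at a mean of 11.2% of the matched regions (central 95% of draws 7.56 to 15.1, lowest 6.22). Without matching, it was found at 3.198% (3.07 to 3.34) of the day 10 regions that were absent from the day 5 list. GATA6 was found at 30.2%, within the range of the draws (mean 29.6%, 24.9 to 35.1). Without matching, day 5 regions were more frequent at HNF6 regions with GATA6, with an odds ratio of 4.09 (3.07 to 5.44). It was 1.82 (1.34 to 2.47) with the coarser matching by HNF6 score deciles and 1.49 (1.10 to 2.03) within score and width deciles. The finer matching of the draws showed no such excess, with 427 of 1000 draws as large. Score differences left within deciles may therefore account for the ratio of 1.82. The 225 regions were wider, with a median of 399 bp against a mean of 367 bp in the draws (348 to 388). Counted from the day 5 list, 66 of 250 regions, or 26.4% (21.3 to 32.2), overlapped a listed GATA6 region and 5, or 2.0% (0.857 to 4.60), an NKX6.1 region. Shifted day 5 lists overlapped NKX6.1 in 0 to 5 regions. Among regions above the median score of each list, GATA6 fell to 8.8% (11 of 125) and NKX6.1 to 0 of 125. That limit also cut the GATA6 and NKX6.1 lists. At all listed GATA6 regions, the share by day 5 score quartile was 27.0, 27.4, 21.0 and 30.2%, from lowest to highest. The GATA6 regions at day 5 regions had a lower median GATA6 score, 75 against 103 for the others. With equal numbers of strongest regions, all 250 day 5 regions were set beside only the 250 strongest of each other list. GATA6 then fell to 1.6% and NKX6.1 to 0 of 250. With 50% of the shorter region covered, NKX6.1 fell to 0.8%.

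GATA6 and HNF6 on day 10 were compared to find where both factors occupied the same regions in progenitors. All 6285 listed GATA6 regions overlapped an HNF6 region. How the partial list was chosen is not given in the sources used here. A list cut to peaks at HNF6 regions would give this share by construction. Neither this share nor its ratio to chance was therefore taken to measure co-occupancy. From the HNF6 side, 6269 of the 64919 regions overlapped a listed GATA6 region. These had a median HNF6 score of 235 against 77 for the others, and 36.7% of them were in the highest score decile against 7.15% of the others. The share with GATA6 was 5.70% (5.16 to 6.29) in the lowest HNF6 score decile, stayed between 4.14% and 6.95% up to decile 7, and reached 35.4% (34.2 to 36.6) in the highest. Midpoints of the 6339 overlapping pairs lay a median of 63 bp apart, and the scores of the pairs had a Spearman's rho of 0.18 across regions.

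The strongest GATA6 region lay on chromosome 5 at 93621672 to 93622251 (score 4394), followed by chromosome 6 at 109225036 to 109225489 (score 3911) and chromosome 2 at 145222182 to 145222698 (score 3766). The last 2 of these also overlapped an NKX6.1 region. Of the 10 strongest GATA6 regions, 4 overlapped an NKX6.1 region and 2 an HNF6 region of day 5. With equal numbers of strongest regions in each list, 36.5% of the GATA6 regions overlapped one of the HNF6 regions. That setting kept all 6285 listed GATA6 regions, each of which overlaps an HNF6 region, so this share does not measure co-occupancy either.

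**Figure D2:**
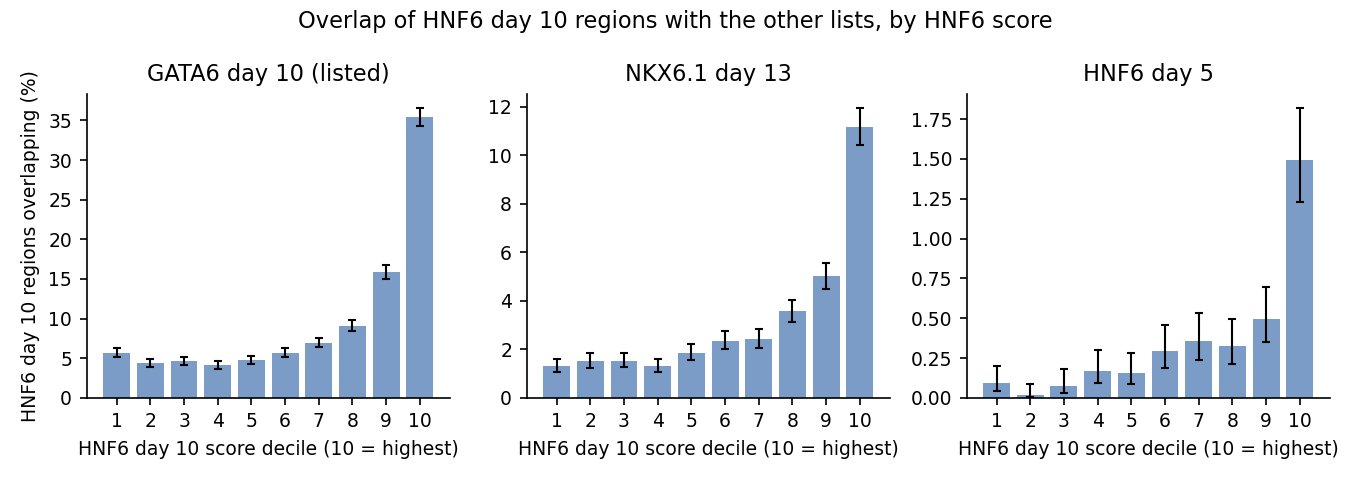
Share of HNF6 day 10 regions (in percent) that overlapped a listed GATA6 region of day 10, an NKX6.1 region of day 13 or an HNF6 region of day 5, by decile of the HNF6 score, with Wilson 95% intervals; the vertical scales differ. From the lowest to the highest decile the shares went from 5.70% to 35.4%, from 1.29% to 11.2% and from 0.0924% to 1.49%.

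NKX6.1 on day 13 was compared with HNF6 on day 10 to find how much of the NKX6.1 occupancy lay at regions held by HNF6 earlier. Most NKX6.1 regions lay elsewhere: 2097 of 14627, or 14.3% (13.8 to 14.9), overlapped an HNF6 region. That was 15.9 times the mean of 131.6 in shifted lists (range 95 to 169), and 12.7 times the mean when each region was moved by only 20 to 200 kb. The ratio was 26.2 among regions above the median score of each list and 29.2 with equal numbers of strongest regions. Stronger NKX6.1 regions overlapped HNF6 more often, with 9.79% (8.87 to 10.8) in the lowest score quartile and 23.2% (21.9 to 24.6) in the highest. Seen from HNF6, 2076 regions overlapped NKX6.1, with a median HNF6 score of 213 against 78 for the others. The share rose from 1.29% (1.05 to 1.60) in the lowest HNF6 score decile to 11.2% (10.4 to 12.0) in the highest. Factor, antibody, day and library changed together between these lists and cannot be told apart. With the 14627 strongest HNF6 regions in place of all, 7.73% of the NKX6.1 regions overlapped.

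The strongest NKX6.1 regions included sites with and without the other factors. The strongest, on chromosome 5 at 5362647 to 5362841 (score 1398), and the next, on chromosome 7 at 17151296 to 17151450 (score 1032), overlapped neither HNF6 nor listed GATA6 regions. The regions on chromosome 5 at 67424800 to 67425156 (score 1022) and on chromosome 2 at 117086874 to 117087114 (score 977) overlapped both. Of the 10 strongest NKX6.1 regions, 5 overlapped an HNF6 region, 6 a listed GATA6 region and 0 an HNF6 region of day 5. The region with GATA6 but no HNF6, on chromosome 7 at 8574333 to 8574505 (score 893), touched a GATA6 region whose own overlap with HNF6 lay outside it. NKX6.1 regions were also found near HNF6 regions without touching them. Among those with no overlap, 8.50% (8.03 to 9.003) had an HNF6 midpoint within 1 kb, against a mean of 3.46% for shifted regions that likewise touched no HNF6 region. Within 0.2 kb the share was 0.384% (0.289 to 0.508) against 0.107%, and within 5 kb it was 27.5% (26.7 to 28.3) against 17.9%.

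NKX6.1 was found far more often at HNF6 regions that also carried GATA6 than at those without it. It occupied 745 of 6269 HNF6 regions with GATA6, or 11.9% (11.1 to 12.7), and 1331 of 58650 without, or 2.27% (2.15 to 2.39), an odds ratio of 5.81 (95% interval 5.29 to 6.38). Because regions with GATA6 had higher HNF6 scores, the ratio was also taken within HNF6 score deciles, where it was 3.10 (2.80 to 3.43). Within HNF6 width deciles it was 3.51 (3.17 to 3.88), and within both 2.93 (2.64 to 3.25). The share was higher with GATA6 in all 10 score deciles, with 6.22% (4.18 to 9.15) against 0.996% (0.777 to 1.28) in the lowest and 16.3% (14.9 to 17.9) against 8.35% (7.55 to 9.22) in the highest. Counted from the NKX6.1 list, 757 of 14627 regions, or 5.18% (4.83 to 5.55), overlapped a listed GATA6 region, 54.8 times the mean of 13.8 in shifted lists (range 2 to 29). These values concern GATA6 regions that also have HNF6, since no other GATA6 region was listed.

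**Figure D3:**
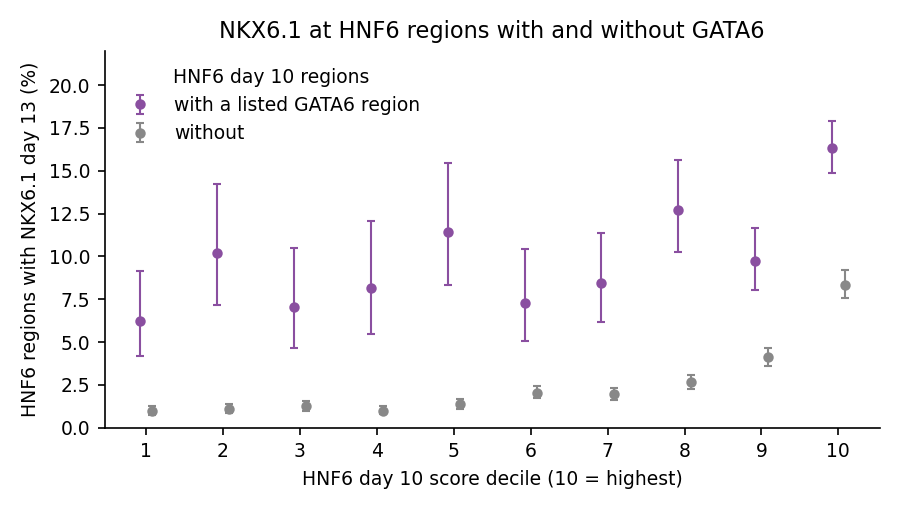
Share of HNF6 day 10 regions with an NKX6.1 region of day 13 (in percent), by decile of the HNF6 score, for regions with (purple, 6269 regions) and without (grey, 58650 regions) a listed GATA6 region; bars are Wilson 95% intervals. The purple points lie above the grey points in all 10 deciles, from 6.22% against 0.996% to 16.3% against 8.35%.

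Regions that held all 3 factors were counted after the HNF6 and GATA6 lists of day 10 and the NKX6.1 list of day 13 had been merged. Of 77349 merged regions, 781 held all 3, which was 12.6% (11.8 to 13.4) of the 6215 with HNF6 and GATA6. Shifting the NKX6.1 list gave a mean of 18.7 (range 7 to 33), so the observed number was 41.7 times chance. Another 5434 merged regions held HNF6 and GATA6 alone, 1330 held HNF6 and NKX6.1 alone, 57319 held only HNF6 and 12485 only NKX6.1. The shared regions had a median HNF6 score of 371, against 79 for the HNF6 list, and 6 of them were also HNF6 regions on day 5. The best mean rank over the 3 lists was that of chromosome 5 at 55584368 to 55585078, with scores of 2348 for HNF6, 1560 for GATA6 and 604 for NKX6.1. Chromosome 3 at 50248067 to 50248520 (2868 for HNF6, 829 for GATA6 and 883 for NKX6.1) and chromosome 3 at 157573946 to 157574497 (2731, 889 and 730) followed. Raw ranks were averaged, although the lists differ in length. Taken as percent of each list, the mean rank of chromosome 5 at 19880508 to 19881846 was 0.90. That was ahead of the chromosome 3 regions, at 1.57 and 1.46. Counted as HNF6 regions that overlapped both other lists, the number was 745. It fell to 674 with 50% of the shorter region covered and to 628 with midpoints within 200 bp. It was 261 among regions above the median score of each list, 405 at scores of at least 50 and 215 with equal numbers of strongest regions.

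Like the regions of every other list, HNF6 regions of day 10 had a near neighbour more often than randomly placed regions. Another HNF6 region lay within the neighbour distance stated with the processing for 55.0% of the HNF6 regions of day 10. The mean was 42.7% when the same number was placed at random on each chromosome. The share was 14.8% against 5.37% for the listed GATA6 regions and 17.8% against 12.2% for NKX6.1. For HNF6 on day 5 it was 3.2% (8 of 250 regions) against 0.176%. Random placement also reaches closed chromatin. Each listed GATA6 region overlaps an HNF6 region, so the GATA6 share may follow from that of HNF6. HNF6 regions with no HNF6 neighbour at that distance overlapped listed GATA6 in 7.90% (7.60 to 8.22), and those with 3 or more neighbours in 14.5% (13.7 to 15.4). For NKX6.1 the shares were 2.80% (2.62 to 2.998) and 4.39% (3.91 to 4.93), and for HNF6 on day 5 they did not rise, at 0.384% (0.319 to 0.461) and 0.320% (0.208 to 0.494). The window of 1 Mb with most HNF6 regions, on chromosome 15 at 53000001 to 54000000, held 84 HNF6, 12 GATA6 and 20 NKX6.1 regions and none of the day 5 list. The window with most NKX6.1 regions, on chromosome 10 at 114000001 to 115000000, held 22 of them with 52 HNF6 and 9 GATA6 regions. The windows and neighbour counts were chosen after the data had been examined.

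**Figure D4:**
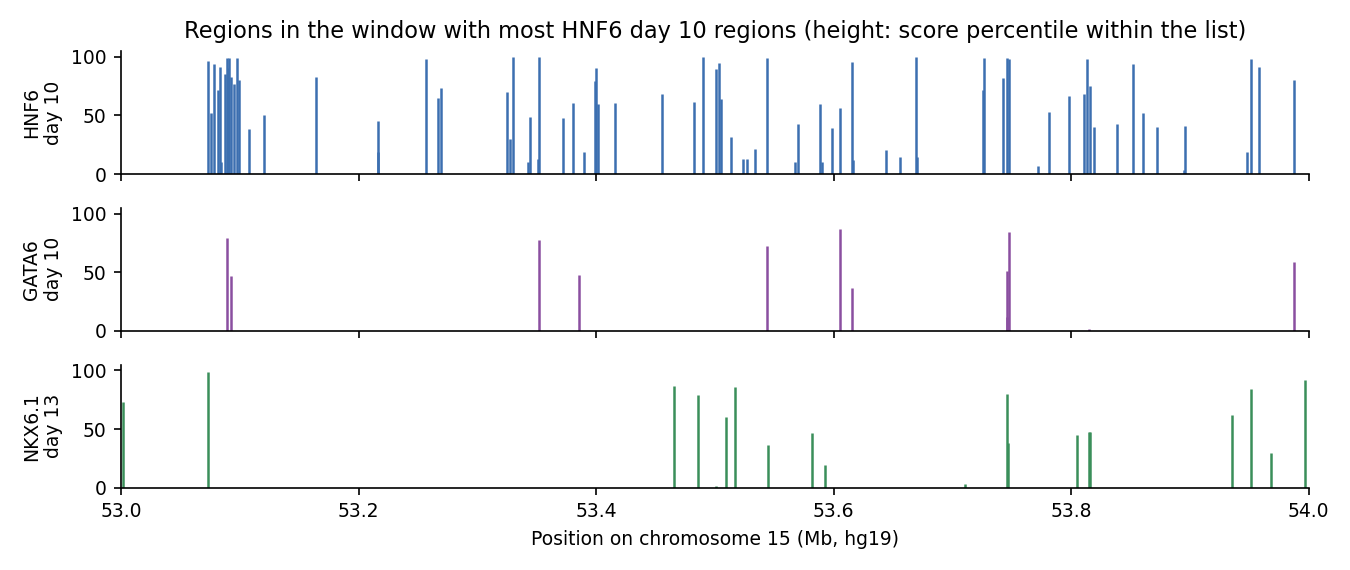
Regions of HNF6 and GATA6 on day 10 and NKX6.1 on day 13 along chromosome 15 from 53000001 to 54000000 (position in Mb, hg19); each line is a region and its height is the score percentile within its own list. The window holds 84 HNF6, 12 GATA6 and 20 NKX6.1 regions.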

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

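Scores of at least 50, the odds ratios within strata and all alternatives for day 5 at GATA6 and at NKX6.1 were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out in turn. Of 43 ratios to chance under the alternatives, 41 stayed above 1. The 6 of these for GATA6 at HNF6 may be fixed by the partial listing and say nothing about stability. The 6 for day 10 at day 5 count the same overlap as the 6 for day 5 at day 10, seen from the other list. All alternatives reuse the same regions, so the ratios are not separate checks. The ratios ran from 84.1 to 1667 for day 5 at day 10, 84.0 to 1522 for day 10 at day 5, 12.7 to 29.2 for NKX6.1 at HNF6, 42.5 to 79.3 for NKX6.1 at GATA6 and 164 to 419 for day 5 at GATA6. The remaining 2 were 0.0 for day 5 at NKX6.1 above the median score (0 of 125 regions, 0.128 by chance) and 0.0 with equal numbers (0 of 250, 0.008 by chance), where chance itself gives less than 1 region. The same limit holds for the ratios of 1667 and 1522, with 0.021 and 0.023 regions by chance. It also holds for day 5 at GATA6, with 0.019 to 0.306 by chance. Shares moved by more than their 95% interval as follows, and the cause was not tested except where fewer regions entered by construction. With 50% of the shorter region covered, GATA6 at HNF6 was 90.6%, NKX6.1 at HNF6 13.1%, NKX6.1 at GATA6 4.81% and day 5 at NKX6.1 0.8%. With midpoints within 200 bp, day 5 at day 10 was 85.6%, GATA6 at HNF6 89.8% and NKX6.1 at HNF6 13.6%. Among regions above the median score of each list, day 5 at day 10 was 84.0%, GATA6 at HNF6 80.0%, NKX6.1 at GATA6 4.44%, day 5 at GATA6 8.8% and day 5 at NKX6.1 0.0%, and regions of all 3 factors numbered 261. At scores of at least 50, day 10 at day 5 was 0.411%, GATA6 at HNF6 87.2%, NKX6.1 at HNF6 15.7%, NKX6.1 at GATA6 5.85%, day 5 at GATA6 19.8% and regions of all 3 numbered 405. With equal numbers of strongest regions, day 5 at day 10 and day 10 at day 5 were both 14.0%, GATA6 at HNF6 36.5%, NKX6.1 at HNF6 7.73%, NKX6.1 at GATA6 7.08%, day 5 at GATA6 1.6%, day 5 at NKX6.1 0.0% and regions of all 3 numbered 215. These numbers of all 3 count HNF6 regions, of which there were 745 at 1 bp, beside 781 merged regions. There were 674 with 50% of the shorter region covered and 628 with midpoints within 200 bp. The limit at the median score left 125, 32460, 3143 and 7314 regions for HNF6 day 5, HNF6 day 10, GATA6 and NKX6.1, and scores of at least 50 left 7848 for NKX6.1. The odds ratio of NKX6.1 by GATA6 went from 5.81 to 3.10 within HNF6 score deciles and to 3.51 within width deciles. The comparisons planned on position relative to genes, genes near regions and motifs, with their other windows, backgrounds and thresholds, were not run. Depth is unknown from the lists, so a region missing from the day 5 list was only not listed, and whether it was occupied was not tested.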

Other observations

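The 3 patterns weighed here were noticed in the data and tested on the same data. The tests of chromosome counts, of day 5 regions at NKX6.1 and of the highest score quartile of NKX6.1 were chosen only after the result was seen, as were the window counts and contigs. Over 3061 windows of 1 Mb, the numbers of NKX6.1 regions on day 13 and HNF6 regions on day 10 had a Spearman's rho of 0.71 across windows, of which 198 were empty in both lists, and of 0.59 over the 2671 windows with regions of both. HNF6 on day 5 had a rho of 0.01 with HNF6 on day 10 and -0.02 with NKX6.1, but 2837 windows held no day 5 region, so these values are mostly ties and are no contrast to the others. Over windows with regions of both lists, rho was -0.11 with HNF6 on day 10 (224 windows) and -0.21 with NKX6.1 (211 windows). No window held more than 3 day 5 regions. The densest windows for HNF6 after that on chromosome 15 were chromosome 18 at 54000001 to 55000000, with 72 HNF6, 12 GATA6 and 10 NKX6.1 regions, and chromosome 14 at 85000001 to 86000000, with 66, 3 and 12. Chromosome 5 at 124000001 to 125000000 also held 66 HNF6 regions, with 8 GATA6 regions, 12 NKX6.1 regions and 1 region of the day 5 list. The window with most GATA6 regions was chromosome 12 at 89000001 to 90000000, with 15 beside 61 HNF6 regions. Of the regions on unplaced contigs, 8 HNF6 and 3 NKX6.1 regions lay on the same contig, chrUn_gl000220.

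The day 5 HNF6 list was short, and 90.4% of it lay in the day 10 list. Recovery without specificity in every library is argued against by NKX6.1, which held 2.0% of it (upper bound 4.60), but listed GATA6 held 26.4%, so recovery common to the HNF6 and GATA6 libraries alone stays open. Selection of day 10 sites by score alone is argued against by the chromosome counts, whose distance from score-matched draws was 129.8 (highest of 1000 draws 46.9). A shallower or less efficient day 5 library that detects mainly strong sites stays open, because the median percentile of 84.7 lay between the bounds of 90 and 75 set before the test. Values outside that test went both ways. Of the day 10 regions with a day 5 region, 43.1% were in the highest score decile. However, only 35 of the 250 strongest day 10 regions overlapped a day 5 region, and the scores of the pairs had a rho of 0.01. Also open and untested are a difference in GC content or open chromatin between the libraries, which may raise chromosome 19, and the biological hypothesis that HNF6 occupies few sites in gut tube endoderm.

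Most NKX6.1 regions of day 13 had no HNF6 region of day 10. Their narrowness is argued against as the cause, since widening them to the median width of HNF6 regions raised the share by 1.10 times, to 15.8%. Weak regions may dilute the share, which was 2.37 times as high in the highest as in the lowest score quartile. They are not the whole cause, because 23.2% of the highest quartile overlapped HNF6 and 76.8% did not. Day, factor, antibody and library changed together, and whether the settings of the peak calling also differed is not given. A biological difference between NKX6.1 and HNF6 sites and a gain of sites after day 10 therefore both stay open and untested.

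NKX6.1 was more frequent at HNF6 regions with listed GATA6, with an odds ratio of 5.81. HNF6 score accounts for part of it, since the ratio within score deciles was 3.10 (2.80 to 3.43). A decile ratio above 1 does not by itself exclude score. For day 5 by GATA6 it was 1.82, while draws with finer matching showed no excess. Score as the whole is argued against mainly by deciles that span few scores. The share was higher with GATA6 in all 10 deciles, also in the lowest, which spans scores of only 13 to 32 (6.22% against 0.996%). The highest decile spans scores of 392 to 4510 and held 375 of the 745 HNF6 regions with both, so score differences may remain within it. Finer matching on score was not done for NKX6.1 by GATA6. Width is argued against as the whole by the ratio within width deciles, 3.51 (3.17 to 3.88). A more open chromatin at such sites, which may raise recovery of every factor, was not tested without the inputs. Whether any GATA6 peaks not analysed here lie at HNF6 regions is not given in the sources used here. If some do, the group without GATA6 holds regions that have it. Joint occupancy of GATA6 and NKX6.1 in progenitors is a biological hypothesis that these lists do not decide.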
